A study of Mus musculus with 8 samples.

How the data were processed

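Gene expression was measured with Illumina MouseRef-8 v2 bead arrays, which hybridize labelled RNA to gene-specific probes carried on beads. Total RNA came from mouse embryonic fibroblasts (MEFs) and from liver, each in 4 genotypes: wild type, Dnmt2-/-, Nsun2-/- and double knockout. There was 1 array for each of the 8 groups, and the groups were taken from the sample labels. Per the labels, RNA was extracted with Trizol and biotin-labelled cRNA was hybridized. With 1 array per group, the number of arrays limits the precision.

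The deposited table that was not normalized holds, per array and probe, an intensity that its values show to be linear with no background subtracted. It also holds a detection p-value for each deposited intensity, named per the file headers; how that p-value was computed is not given in the sources used here. A second deposited table holds the authors' processed intensities. The normalization the authors used is not given in the sources used here. Set against the intensities that were not normalized, the authors' values had rank correlations of at least 0.999 on every array and lay on a linear scale with no centring of genes. Their medians were 104.0, 104.0, 104.2 and 103.7 in wild-type, Dnmt2-/-, Nsun2-/- and double knockout MEFs, and 107.9, 107.2, 107.8 and 107.9 in the livers in the same order. How these columns were brought to similar medians stays unknown.

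Intensities were background-corrected with the normexp model of limma, with background estimated from the detection p-values and an offset of 16 added. They were then put on the log2 scale and quantile-normalized over all 8 arrays. The platform annotation gave 1 gene symbol for 23898 of the 25608 probes, several for 0 and none for 1710. The entrez identifiers of 23882 probes were found in a RefSeq gene table of the assembly GRCm38.p6, and 0 symbols needed updating. That table served only for names and for which genes are neighbours. Each of the 16559 genes was represented by its probe with the highest mean normalized signal, a choice that mattered for the 4757 genes with more than 1 probe. A probe was called detected at a detection p-value under 0.01.

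Each knockout array was compared with the wild-type array of its sample type, over genes detected on at least 1 of the 2 arrays. Differences are log2 differences, and a gene counted when its difference was at least 2-fold. Where a probe was not detected on one array, its value there was set to the higher of its own value and the lowest value among detected probes, and the fold is given as "at least". No p-value was computed for these comparisons. For 47 gene lists, the median difference of the detected members was placed among the medians of 10000 random lists of the same size matched on mean expression. A percentile of 0 or 100 means lower or higher than all of the random lists. Lists with fewer than 5 detected genes have no percentile, and a list is described where it lay among the lowest or highest 2.5% of random lists. The percentile describes these arrays only.

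Tests used limma with Benjamini-Hochberg adjustment at 0.05 on the 10491 genes detected on at least 2 of the 8 arrays. One fit estimated the effects of Dnmt2 loss and of Nsun2 loss over both sample types, with sample type as a covariate and 4 residual degrees of freedom. A fit with the interaction of both genotypes had 3. A nested fit estimated each effect within each sample type, and its difference between liver and MEFs, with 2. The spread in these fits is the departure of arrays from the layout, not the spread between replicate animals or cultures. With no effects, a share of 0.05 of the tested genes would have an unadjusted p under 0.05. Counts at that level are therefore not by themselves a sign of effects. For each gene list the p-values were also adjusted over the list alone. In these fits, and in pairs of differences that share no array, a probe that was not detected enters at its measured value near background, so such changes are not bounds. Pairs of differences that share no array were compared by their correlation across genes, which are not independent replicates.

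On simulated data with 200 changed genes among 10491, the fit over both sample types recovered 91% of genes changed by 1 on the log2 scale with Dnmt2 loss and 87% with Nsun2 loss, and 100% of those changed by 2. For Dnmt2 loss in MEFs the nested fit recovered 41% and 97%, and for Nsun2 loss in MEFs 19% and 98%. The interaction fit recovered 4% and 79%. False calls numbered 17, 13, 13, 5 and 9 in the same order. The simulated noise was independent between arrays, with the spread of the nested fit, and left out effects that differ between MEFs and liver. In the real data, limma gave Fastkd3 (−1.61, Nsun2 loss over both sample types) an adjusted p of 0.139. For Tfap2b (5.09, Dnmt2 loss in MEFs) it was 0.158. The shares recovered may therefore overstate what the fits can find, and 0 calls do not mean that 2-fold effects are absent. Of 100 random lists of 40 genes shifted by 0.5 on the log2 scale, 100 passed the percentile limits in the tested MEF comparison and 100 in the tested liver comparison. Of the unshifted lists 6 and 1 did. The simulated genes varied independently, so this does not cover lists whose genes vary together.

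The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text draws from the 12 genes with the highest and the 12 with the lowest difference of each comparison, up to 4 members of a described list in the direction of its median and up to 2 against it, the 10 largest effects past a test's threshold or else the 5 with the lowest p, and the 10 genes that moved furthest in both of 2 pairs sharing no array. Trdmt1, Nsun2, Xist and Y-linked genes are always given. Symbols of predicted genes were counted and could be passed over. The alternatives were quantile normalization within each sample type, no background correction, an offset of 50, scaling to the same median, the authors' deposited values, a detection p-value under 0.05, detection on both arrays, every probe counted, no detection filter, an intensity trend in the prior of limma, an added interaction term and leaving out each array in turn. Counts without genes of the X and Y chromosomes, and fits over a list without each MEF array or under another normalization, were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.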

Results

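Gene expression was compared between mice and cells lacking the RNA methyltransferase Dnmt2 (gene symbol Trdmt1), Nsun2 or both, and their wild-type counterparts. Both enzymes methylate cytosines in transfer RNAs. The sample types were mouse embryonic fibroblasts (MEFs), taken at embryonic day 13.5, immortalized with the SV40 large T antigen and used at passage 9, and livers of mice aged 2 months. Each of the 8 groups had 1 array, so no difference between 2 arrays had a replicate check. The labels give the mice a mixed background, and differences in background between arrays cannot be told apart from genotype. Of 25608 probes, 13019 to 13409 were detected on the MEF arrays and 11585 to 11688 on the liver arrays. The median intensity per array was 99.8 to 111. It was 89.7 to 94.7 for those undetected probes that had the highest detection p-values, so many probes lay near background. Log2 intensities before background correction and normalization were correlated across probes. Between wild-type, Dnmt2-/- and Nsun2-/- MEFs r was 0.986 to 0.989. Between double knockout MEFs and each of the other MEF arrays it was 0.978 to 0.979. Between 2 livers it was up to 0.993, and between a MEF and a liver array 0.669 to 0.682.

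The targeted genes were examined first. Nsun2 had a log2 signal of 5.36 in wild-type MEFs and 5.14 in Dnmt2-/- MEFs, and was not detected in Nsun2-/- (4.33) or double knockout MEFs (4.22). In liver it was 5.35 in wild type and was not detected in Nsun2-/- (4.10) or double knockout (4.19). It was also not detected on the liver array labelled Dnmt2-/- (4.41). Its intensity there before normalization, 99.7, lay between wild type (109) and the Nsun2-/- (87.7) and double knockout (92.2) livers. The Nsun2 probe lay near background, so it does not settle whether that array lacks Nsun2. Every comparison with this array carries this limit. Fastkd3, a gene near Nsun2 on its chromosome, was 6.41 on that array, 6.13 in wild type, 5.17 in the double knockout and not detected in the Nsun2-/- liver (4.69). The brightest Trdmt1 probe lay near background: it was detected in Dnmt2-/- MEFs (5.09) and double knockout MEFs (4.64), and not in wild-type MEFs (4.51), Nsun2-/- MEFs or any liver. Its measured values in the wild-type, Dnmt2-/-, Nsun2-/- and double knockout livers were 4.31, 4.87, 4.15 and 4.64, higher where the label lacks Dnmt2, as in MEFs. Where this probe lies relative to the deleted part of Trdmt1 is not given in the sources used here, so it does not check the labels.

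**Figure D1:**
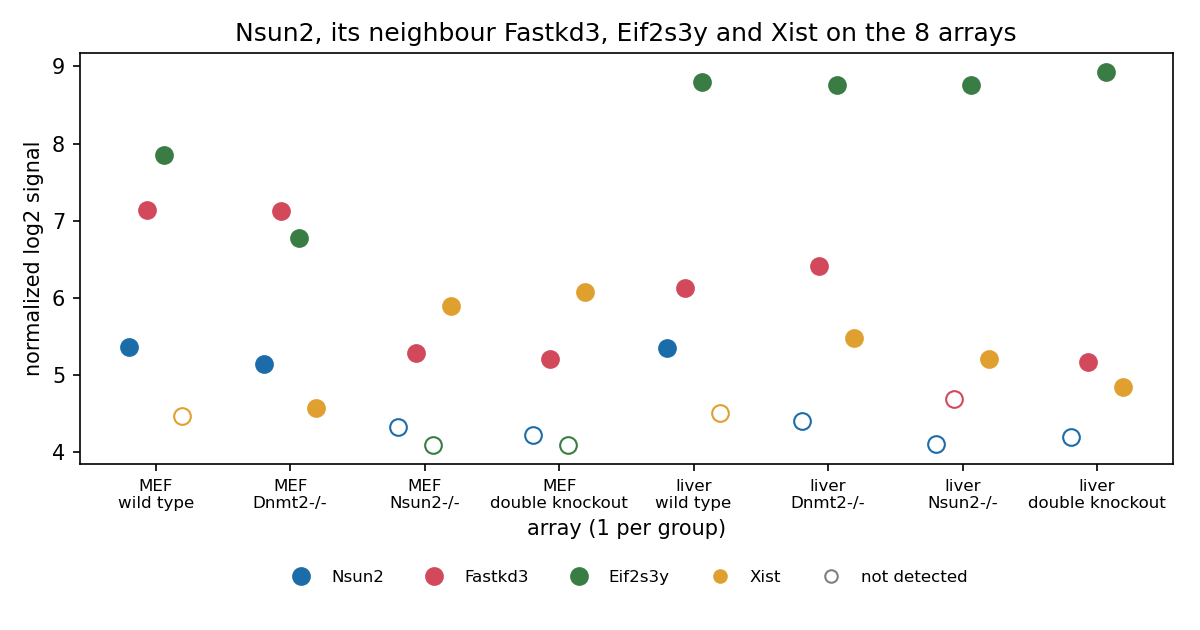
Normalized log2 signals of Nsun2, its neighbour Fastkd3, Y-linked Eif2s3y and Xist on each of the 8 arrays, with filled markers where the probe was detected and open markers where it was not. Nsun2 was detected in wild-type MEFs (5.36), Dnmt2-/- MEFs (5.14) and wild-type liver (5.35) and on none of the other arrays.

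Markers of both sample types followed the labels. The median log2 signal of the extracellular matrix and fibroblast genes was 10.42, 10.47 and 9.33 in Dnmt2-/-, Nsun2-/- and double knockout MEFs, between the last 2 of these in wild-type MEFs, and 4.84 to 4.97 in the livers. That of the hepatocyte secreted proteins was 12.48 to 12.59 in the livers and 4.22 to 4.29 in MEFs. The Y-linked gene Eif2s3y was 7.85 in wild-type and 6.78 in Dnmt2-/- MEFs and was not detected in Nsun2-/- or double knockout MEFs. Y-linked Kdm5d was 5.95 and 5.70 in the former and not detected in the latter, whereas Xist, transcribed from the inactive X chromosome, was 5.90 in Nsun2-/- and 6.07 in double knockout MEFs, 4.58 in Dnmt2-/- and not detected in wild type by the same probe. Sex-linked expression and Nsun2 genotype therefore cannot be separated in the MEFs. In the livers Eif2s3y was 8.79, 8.76, 8.76 and 8.93, and Kdm5d was detected in all except Nsun2-/-. Xist by the same probe was 5.48, 5.21 and 4.85 in the 3 knockout livers and not detected in wild type. A second Xist probe was detected among the livers only in Nsun2-/- (5.16). In MEFs that second probe was detected in wild type (4.62), Nsun2-/- (5.88) and double knockout (6.19). Of the other Y-linked genes, the probe of Uty was detected on all 8 arrays, while Usp9y, Zfy1, Zfy2 and Sry were detected on none.

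The Dnmt2-/- MEF array was set against wild-type MEFs to ask which transcripts differ without Dnmt2. The protease inhibitor Serpina3n was 32.7-fold higher, Wfdc2 28.6-fold, the water channel Aqp1 19.2-fold, the matrix metalloproteinase Mmp3 15.4-fold and the extracellular matrix glycoprotein Tnn 13.5-fold. The transcription factor Tfap2b was at least 16.7-fold higher, the chemokine Cxcl15 at least 14.6-fold and Angptl7 at least 12.1-fold, each not detected in wild type. Lcn2, which binds iron carriers of bacteria, was 11.3-fold higher, the small proteoglycans Lum and Prelp 9.80-fold and 9.17-fold, and the chemokine Cxcl9 9.07-fold. Igfbp5, which binds insulin-like growth factors, was 7.67-fold lower, the cationic amino acid transporter Slc7a3 6.65-fold, Ifi202b 5.48-fold, Ccl27a 4.51-fold and the branched-chain aminotransferase Bcat1 4.44-fold. The transcription factors Bcl11b, Sox5 and Hoxd9 were 5.61-fold, 5.09-fold and 4.67-fold lower, Sim2 at least 5.12-fold and Isl1 at least 4.47-fold. In all, 353 of 9742 genes differed at least 2-fold, 266 of them higher and 87 lower. The count was 131 with no background correction, split 112 and 19, and 133 with the authors' deposited values.

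Of the gene lists, 16 stood apart in this comparison. Among 41 interferon-stimulated genes, which cells switch on in antiviral responses, 39 were higher and 15 at least 2-fold, with a median log2 difference of 0.79 (percentile 100). Oas2 was higher by 2.56, Irf7 by 2.10, the immunoproteasome subunit Psmb9 by 1.76 and Ccl5 by 1.63, while Ifi27 (−1.09) and Irgm1 (−0.29) were lower. The inflammatory cytokines and NF-kB targets had a median of 0.51 (percentile 100), led by Cxcl15, Lcn2, the adhesion molecule Icam1 (2.55) and Cxcl5 (1.60), and the extracellular matrix list 0.37 (percentile 100), led by Mmp3, Lum and Fmod (2.08). Among myeloid markers (0.48, percentile 99.9) the class II histocompatibility gene H2-Ab1 was higher by 2.37, its chaperone Cd74 by 1.69 and S100a8 by at least 1.93. Glycolysis and hypoxia targets (0.23), immediate-early genes (0.33) and smooth muscle genes (0.15) also had higher medians, with Car9 higher by 2.03, Dusp1 by 1.15 and Itga1 by 1.18.

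Other lists had lower medians in this comparison, while cytosolic ribosomal proteins (−0.09, percentile 25.4) and fatty acid synthesis (−0.23, percentile 2.78) stayed within the limits. All 22 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, were detected and 19 were lower (median −0.43, percentile 0), with Lars at −0.90, Sars at −0.89, Nars at −0.89 and Aars at −0.88, against Hars at 0.25. Of 46 tRNA modification enzymes 36 were lower (−0.30, percentile 0), among them Mettl1 (−0.95), Dus4l (−0.93) and Trmt1 (−0.90), and of 42 ribosome biogenesis genes 38 were lower (−0.41, percentile 0), among them Rrp12 (−0.94) and Nop2 (−0.87). None of these 3 lists held a gene that was 2-fold lower. The ATF4 targets of the integrated stress response had a median of −0.44 (percentile 0), with Slc7a3 at −2.73, asparagine synthetase Asns at −1.40, Chac1 at −1.33 and Gpt2 at −1.27, against Cebpb at 0.71. Cholesterol synthesis genes were at −0.53 (percentile 0), led by Lss (−0.96) and Stard4 (−0.84). Mitochondrial ribosomal proteins (−0.27), the respiratory chain (−0.23), translation factors (−0.19) and cell cycle genes (−0.19) were also lower, with Mrps7 at −0.98, Ndufs8 at −1.03, Pabpc4 at −0.80 and Cdc25c at −0.70. Over the 6 comparisons, 74 of 228 list medians were past the limits, against 11.4 that random lists would give. Random lists hold unrelated genes, so a list whose genes vary together can pass the limits with no effect of genotype. The comparisons of a sample type also share 1 wild-type array.

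**Figure D2:**
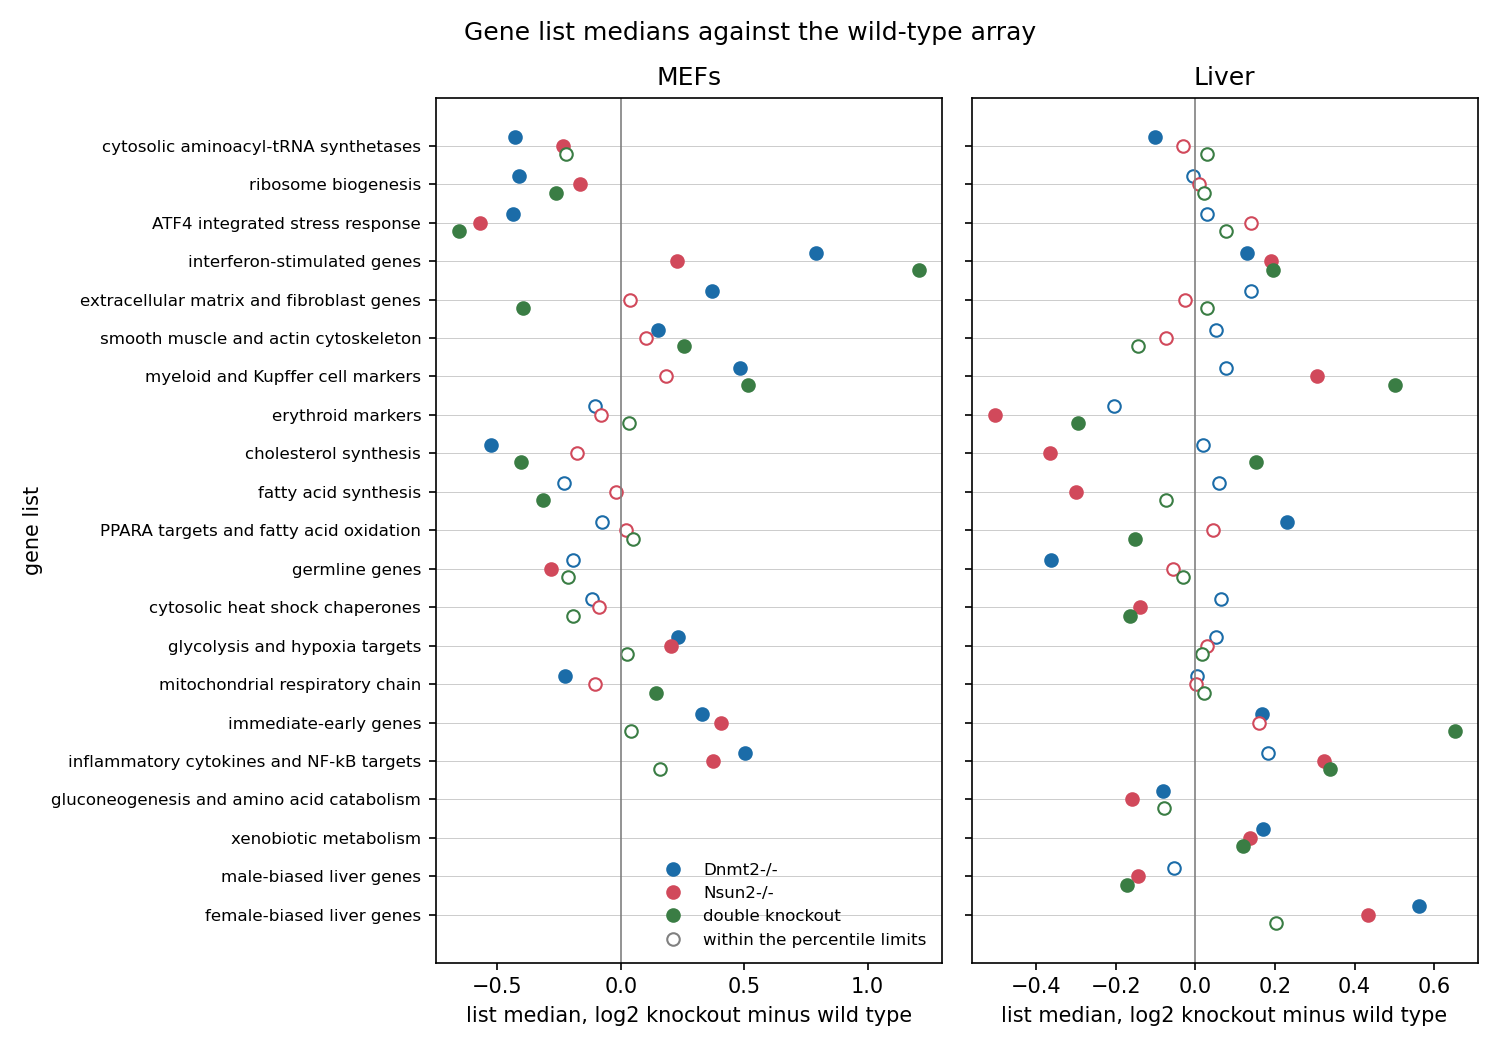
Median log2 difference from wild type of the detected members of 21 gene lists, with MEFs and livers in separate panels and a marker for each knockout; filled markers lie among the lowest or highest 2.5% of 10000 matched random lists and open markers do not. The interferon-stimulated genes had medians of 0.79, 0.23 and 1.21 in Dnmt2-/-, Nsun2-/- and double knockout MEFs.

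The Nsun2-/- MEF array was set against wild-type MEFs to ask which transcripts differ without Nsun2. The guanylate-binding protein gene Gbp2b was at least 22.0-fold higher, Plac8 11.4-fold, Prelp 10.5-fold, Lcn2 9.31-fold, Aqp1 9.09-fold and the complement inhibitor Serping1 7.79-fold. H2-Ab1 was 7.58-fold higher, the homeobox gene Meox2 at least 7.13-fold, Mmp3 6.63-fold, smooth muscle actin Actg2 6.10-fold, the angiotensin receptor Agtr1a 6.06-fold and Errfi1, an inhibitor of ErbB receptors, 5.88-fold. Igfbp5 was 9.47-fold lower, Bcl11b at least 7.48-fold, Trim59 at least 5.95-fold, Slc7a3 4.92-fold, the vasopressin receptor Avpr1a 4.64-fold, the transcription factor Gata6 4.31-fold and Hoxc9 3.37-fold. Fastkd3 and Zfp367, on the same chromosome as Nsun2, were 3.62-fold and 3.44-fold lower, and Y-linked Eif2s3y was not detected. A second probe of Zfp367 was higher by 0.36, and one of Dppa5a, at least 3.87-fold lower by its brightest probe, was higher by 0.34. In all, 254 of 9677 genes differed at least 2-fold, 188 higher and 66 lower. The count was 95 with no background correction; scaling to the same median gave 191 higher and 122 lower, with the median of all genes at −0.13 in place of −0.05.

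In this comparison 9 lists stood apart. The ATF4 targets had a median of −0.57 (percentile 0), with Slc7a3 at −2.30, Chac1 at −1.56, Aldh1l2 at −1.52 and Atf5 at −1.46, against Stc2 at 1.48. Of 22 aminoacyl-tRNA synthetases 17 were lower (−0.23, percentile 0.35), with Sars at −0.98 and Lars at −0.88, and of 40 ribosome biogenesis genes 31 were lower (−0.16, percentile 1.33), with Ubtf at −0.59. Immediate-early genes were at 0.41 (percentile 100), led by Dusp6 (1.30) and Socs3 (1.13), and NF-kB targets at 0.37 (percentile 100), led by Lcn2, Saa3 (2.02) and Icam1 (1.95). Interferon-stimulated genes had a median of 0.23 (percentile 100) with 4 of 41 at least 2-fold higher: Ccl5 (1.85), Oas2 (1.27), Psmb9 (1.19) and Cxcl10 (1.04). Glycolysis and hypoxia targets were at 0.20 (percentile 100), with Aldoc at 2.07 and Adm at 1.83. The hepatocyte secreted proteins, of which 15 of 50 were detected, were split, with 8 higher and 7 lower and a median of 0.38 (percentile 99.95): Apoe was at 1.77 and Cp at 1.30, against Igf1 at −0.62. The germline genes were at −0.28 (percentile 1.98), with Xlr4a at −0.83. Eif2s3y and Kdm5d were not detected on this array and Xist was at 5.90, so this comparison differs in sex-linked expression as well as in Nsun2.

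The double knockout MEFs differed from wild type in more genes than either single knockout did, 660 of 9683, of which 387 were higher and 273 lower. Tfap2b was at least 48.6-fold higher, Csprs at least 21.9-fold, the aldehyde dehydrogenase Aldh3a1 20.8-fold, Aqp1 20.6-fold, H2-Ab1 19.8-fold, the homeobox gene Gsc 16.7-fold, the TGF-beta coreceptor Eng 11.4-fold, H2-Q8 9.71-fold, the gelatinase Mmp9 9.65-fold, Igfbp2 9.32-fold and Wnt6 9.13-fold. The surface glycoprotein Thy1 was 20.7-fold lower, Ankrd1 12.1-fold, Hoxa7 11.7-fold, Slc7a3 11.1-fold, Cavin2 10.4-fold, the matrix protein Fbln2 10.4-fold, Fhl1 10.3-fold and P-cadherin (Cdh3) 7.68-fold. Eif2s3y was at least 10.9-fold lower. A second probe of Fbln2 was higher by 0.32. The count was 254 with no background correction and 253 with the authors' deposited values.

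Of the gene lists, 15 stood apart. All 21 detected Hox genes, which set position along the body axis, were lower (median −1.47, percentile 0), 11 of them at least 2-fold, with Hoxa7 at −3.54, Hoxd9 at −2.67 or below, Hoxd10 at −2.66 or below and Hoxa5 at −2.48. Of 41 interferon-stimulated genes 39 were higher and 23 at least 2-fold (1.21, percentile 100), with Psmb9 at 2.88, Oas2 at 2.49, Psmb8 at 2.45 and Gbp2 at 2.32, against Ifi27 at −0.86 and Oasl1 at −0.45. Myeloid markers were at 0.51 (percentile 100), with H2-Ab1 at 4.31, Coro1a at 2.15, Lyz1 at 1.87 and Cd74 at 1.44. Extracellular matrix genes were at −0.40 (percentile 0), with Thy1 at −4.37, Fbln2 at −3.37, the growth factor Ccn2 at −2.60 and Dcn at −2.51, against Prrx1 at 0.89. The ATF4 targets had a median of −0.66 (percentile 0), with Slc7a3 at −3.48, Aldh1l2 at −2.63, Gpt2 at −1.79 and Chac1 at −1.71. Cholesterol synthesis was at −0.40, fatty acid synthesis at −0.31, endoplasmic reticulum chaperones at −0.30, ribosome biogenesis at −0.26 and cytosolic ribosomal proteins at −0.17, with Stard4 at −0.85, Scd2 at −0.99, Herpud1 at −1.08, Gnl3 at −0.75 and Rplp0 at −1.29. The tRNA modification enzymes (−0.16, percentile 5.18) and aminoacyl-tRNA synthetases (−0.22, percentile 3.51) stayed within the limits. Skeletal muscle genes (0.67), epithelial genes (0.27), smooth muscle genes (0.26), p53 targets (0.22) and the respiratory chain (0.14) were higher, with Tnnc1 at 1.08, Pkp3 at least 1.07, Lmod1 at 0.82, Ephx1 at 1.71 and Atp5o at 0.81.

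Effects of Dnmt2 loss in MEFs were tested over the 2 pairs of arrays that share none, Dnmt2-/- against wild type and double knockout against Nsun2-/-. Within each of these pairs Eif2s3y was detected on both arrays or on neither. With adjustment over the list alone, 27 of 41 interferon-stimulated genes rose and 0 fell by limma, among them Irf7 by 1.90 (SE 0.19, adjusted p 0.00616), Oas2 by 1.89 (SE 0.34, adjusted p 0.00956), Psmb9 by 1.72, Gbp2 by 1.68, Psmb8 by 1.54, Trim30a by 1.46, Igtp by 1.37, Ifit3 by 1.20, Gbp3 by 1.17 and Mx2 by 1.16. The list's fitted median was 0.83. It was 0.89 without the wild-type or the Dnmt2-/- MEF array and 0.81 without the Nsun2-/- or the double knockout MEF array. With a MEF array left out, the effect rests on 1 pair of MEF arrays and the spread on the livers. In double knockout minus Nsun2-/- MEFs alone the list median was 0.85 (percentile 100), with 17 of 42 genes at least 2-fold higher. Other lists of Dnmt2-/- against wild type turned round in that pair: NF-kB targets (−0.22, percentile 1.5) and extracellular matrix genes (−0.42, percentile 0). Ribosome biogenesis (−0.09, percentile 11.6) and ATF4 targets (−0.15, percentile 4.36) stayed within the limits. Myeloid markers (0.36, percentile 99.6) and cholesterol synthesis (−0.28, percentile 0.9) kept their direction. Of 24 Hox genes tested, 5 fell with adjustment over the list alone: Hoxa7 by −2.85, Hoxd9 by −2.40 (SE 0.19, adjusted p 0.00126), Hoxd8 by −2.05, Hoxd4 by −1.49 and Hoxa11 by −1.29; Hoxd9, Hoxd4 and Hoxa11 were not detected in double knockout MEFs. Hoxd9, Hoxd8, Hoxd4 and Hoxa11 were detected in no liver, and the fit shares its spread over both sample types, so their adjusted p may be too small. The list's fitted median went from −0.43 to −0.95 without the wild-type or the Dnmt2-/- array and to −0.12 without either of the others. Against wild type the Hox list stayed within the limits in Dnmt2-/- MEFs (−0.19, percentile 5.54, 11 genes higher and 14 lower) and in Nsun2-/- MEFs (−0.05, percentile 42.0). H2-Ab1 (1.88) and Cd74 (1.74) rose over the myeloid list alone, Ephx1 (1.44) and Pltp (1.18) over the p53 targets, and Gap43 fell (−1.31) over the neural genes. Over all tests, 35 of 423 combinations of an effect and a list had at least 1 gene past the threshold over the list alone, against 21.2 that would have with no effects, so single genes that passed in this way may be chance. Over all 10491 genes limma called 0 at an adjusted p of 0.05, with 677 at an unadjusted p under 0.05; the lowest adjusted p was 0.158, for Tfap2b (5.09, SE 0.38), Cacna1h (SE 0.17), Hoxd9 (−2.40) and Igfbp2 (2.96), followed by Sim2 (−2.16, adjusted p 0.165). With arrays scaled to the same median these 5 genes passed, with adjusted p of 0.0421 and 0.0426. Tfap2b, like Hoxd9, was detected in no liver, so its adjusted p may also be too small.

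**Figure D3:**
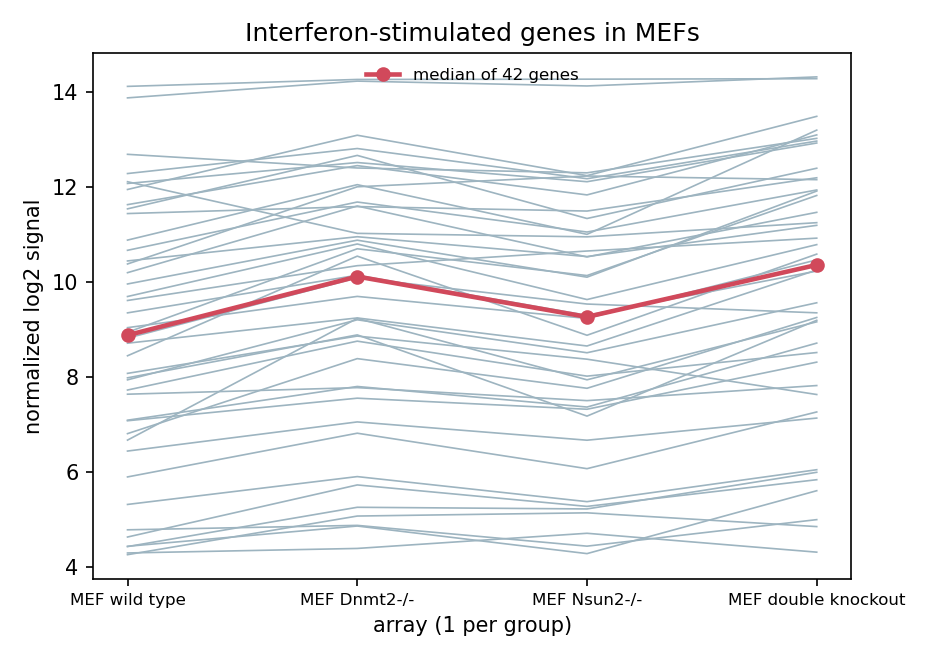
Normalized log2 signals of 42 interferon-stimulated genes on the 4 MEF arrays, with 1 line per gene and the list's median in red. The median was 8.87 in wild-type, 10.11 in Dnmt2-/-, 9.26 in Nsun2-/- and 10.36 in double knockout MEFs.

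**Figure D4:**
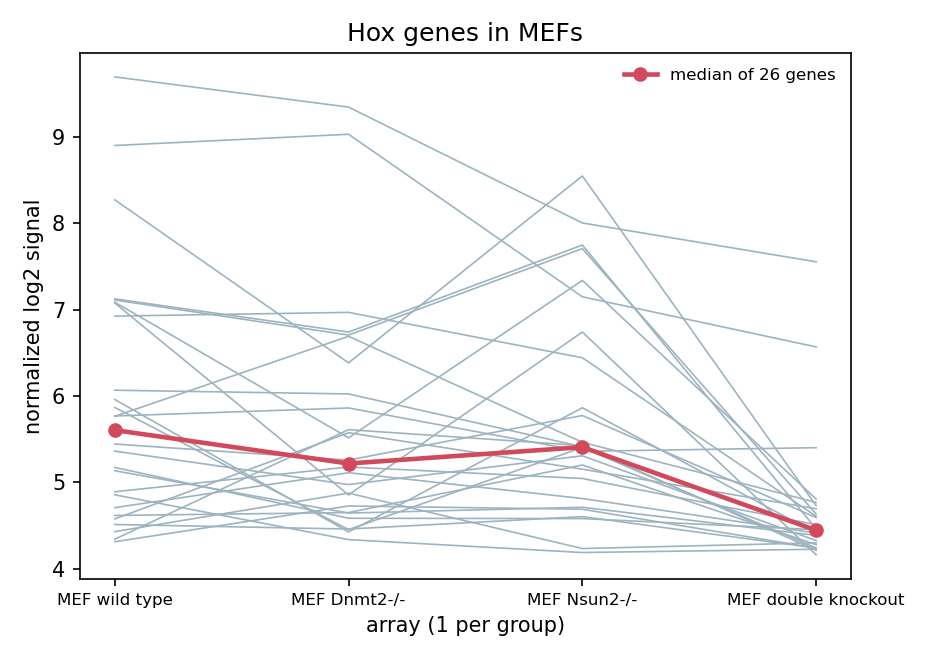
Normalized log2 signals of 26 Hox genes on the 4 MEF arrays, with 1 line per gene and the list's median in red. The median was 5.60 in wild-type, 5.22 in Dnmt2-/-, 5.41 in Nsun2-/- and 4.44 in double knockout MEFs.

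Effects of Nsun2 loss in MEFs were tested in the same way, over Nsun2-/- against wild type and double knockout against Dnmt2-/-. Several lists of Nsun2-/- against wild type turned round in double knockout minus Dnmt2-/- MEFs. These were NF-kB targets (−0.27, percentile 0.31), hypoxia targets (−0.17, percentile 1.41), hepatocyte proteins (−0.29, percentile 0.7) and ribosome biogenesis (0.20, percentile 97.9). Immediate-early genes, aminoacyl-tRNA synthetases and germline genes lay within the limits. ATF4 targets (−0.24) and interferon-stimulated genes (0.24) kept their direction past the limits. Hoxc9 fell by 2.11 (SE 0.23) and Hoxc6 by 1.74 (SE 0.17). Both had an adjusted p of 0.00281 by limma with adjustment over the list of Hox genes alone. Neither gene was detected in any liver, so these adjusted p may be too small. The list's fitted median was −0.35. It was −0.70 without the wild-type or the Nsun2-/- array and 0.02 without either of the others. H2-Ab1 rose by 2.43 (SE 0.34, adjusted p 0.0203) over the myeloid list alone. Eif2s3y and Kdm5d, not detected in either MEF array lacking Nsun2, also passed as lower, and Xist, the only gene of its list and not detected by the same probe in wild type, as higher. Over all genes limma called 0, with 515 at an unadjusted p under 0.05 and a lowest adjusted p of 0.351, for Eif2s3y, Fastkd3 (−1.89), Hoxc6, Avpr1a (−2.62) and Zfp367 (−2.02).

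Across all genes the 2 pairs for the loss of 1 enzyme in MEFs had little in common. For Dnmt2 loss with and without Nsun2, r over 10426 genes was −0.016; 53 genes were at least 2-fold higher and 16 lower in both pairs, while 69 went opposite ways. Independent pairs with as many changed genes would give 8.69, 2.89 and 11.5. Tfap2b was not detected in wild-type or Nsun2-/- MEFs, nor Sim2 in either array lacking Dnmt2. Besides Tfap2b, Igfbp2, Cacna1h, Sim2, Hoxd9 and Hoxa7, the genes that moved furthest in both were Bmp4 (2.89 and 2.15), Csprs, not detected in wild type, Ly6e (1.82 and 2.43) and Tle1 (1.73 and 1.79). For Nsun2 loss r was −0.119, with 21 genes higher and 17 lower in both pairs and 76 opposite, against 4.90, 2.47 and 8.64. The furthest in both were Eif2s3y, Avpr1a, H2-Ab1 (2.92 and 1.94), Scara5 (2.01 and 1.88), Fastkd3, Zfp367, Gdf10, not detected in Nsun2-/- MEFs, Hoxc9, Hoxc6 and Cd59a (1.69 and 2.08).

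The liver array labelled Dnmt2-/- was set against wild-type liver. Nudt6 was 5.47-fold higher, the hormone Fgf21 4.91-fold, Dnaic1 at least 4.69-fold, Paip1 4.39-fold, Selenbp2 4.23-fold, Rgs16, which dampens G protein signals, 3.94-fold, the hepcidin gene Hamp2 3.67-fold, the rhythmic deadenylase Noct 3.58-fold and the apolipoprotein Apoa4 3.28-fold. Obp2a was 16-fold lower, and lower in the other two knockout livers too; the ion channel Asic5 was at least 11.9-fold lower, Psmd8 10.1-fold, the globin Hbb-b2 at least 9.12-fold, Crym at least 5.53-fold, Fgfr1op2 4.96-fold, Nat8 3.94-fold and Mug2 3.65-fold. The brightest probe of the apolipoprotein Apoc2 was 10.6-fold lower, but another Apoc2 probe was higher by 1.35. In all, 211 of 8943 genes differed at least 2-fold, 98 higher and 113 lower. The count was 108 with arrays scaled to the same median, split 65 and 43, and 32 with no background correction. Nsun2 was not detected on this array.

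On this array 9 lists stood apart. All 10 detected female-biased liver genes were higher (median 0.56, percentile 100), with Hamp2 at 1.88, the fatty acid hydroxylase Cyp4a14 at 1.63, Acot3 at 1.60 and Cux2 at least 0.94. Of 35 PPARA targets and fatty acid oxidation genes 30 were higher (0.23, percentile 100), led by Fgf21 (2.29), Cyp4a14, Acot3 and Cyp4a31 (1.00), against Acot2 at −0.81. Xenobiotic metabolism genes were at 0.17 (percentile 100), with Cyp2b10 at 0.84, and interferon-stimulated genes at 0.13 (percentile 99.4), with Cxcl10 higher by at least 1.60 and Irgm1 at 0.99. Immediate-early genes were at 0.17 (percentile 98.0), with Dusp6 at 1.05. The acute-phase list was lower (−0.13, percentile 0.08), with serum amyloids Saa2 at −1.82 and Saa1 at −1.70, Lcn2 at −1.19 and Orm2 at −0.86. Aminoacyl-tRNA synthetases were at −0.10 (percentile 2.17), with Eprs at −0.43, and germline genes at −0.36 (percentile 1.02), with Ddx4 at −0.54 against Xlr4a at 1.51. Gluconeogenesis and amino acid catabolism genes were at −0.08 (percentile 1.33), with Irs2 at −0.68, but at 0.0066 with arrays scaled to the same median.

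The Nsun2-/- liver was set against wild-type liver. Thiopurine methyltransferase Tpmt was 17.2-fold higher, A2ml1 10.2-fold, Dnaic1 at least 9.35-fold, the cytokine signal inhibitor Cish 9.16-fold, Abhd1 7.55-fold, Saa3 6.15-fold, the chemokine Cxcl13 at least 5.16-fold, Selenbp2 4.86-fold and Nudt6 4.70-fold. The transcription factor Olig1 was at least 12.3-fold lower, Hbb-b2 at least 10.9-fold, caspase Casp9 at least 9.50-fold, Obp2a 8.66-fold, Asic5 6.84-fold, the fatty acid-binding protein Fabp5 6.34-fold, Crym at least 5.45-fold, Mul1 4.33-fold and Tsc22d1 4.09-fold. In all, 259 of 8949 genes differed at least 2-fold, 126 higher and 133 lower. The count was 44 with no background correction and 142 with arrays scaled to the same median.

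In this liver 14 lists stood apart. Cholesterol synthesis genes had a median of −0.37 (percentile 0), with Hmgcs1 at −1.27, Nsdhl at −1.07 and Idi1 at −0.87, and fatty acid synthesis genes −0.30 (percentile 0.02), with Thrsp at −1.69 and the regulator Srebf1 at −1.08, against Elovl5 at 0.36. Circadian clock genes were at −0.40 (percentile 0), with Nr1d1 at −1.62, Cry2 at −1.20, Bhlhe40 at −1.17 and Nr1d2 at −0.77, against Arntl at 0.43 and Ciart higher by at least 0.84. Bile acid genes were at −0.15 (percentile 0.12), with the rate-limiting enzyme Cyp7a1 at −1.39, and gluconeogenesis and amino acid catabolism genes at −0.16 (percentile 0), with Bhmt at −0.96 and glucose-6-phosphatase G6pc at −0.76. Female-biased liver genes were higher (0.43, percentile 99.9), with Cyp4a14 at 1.47 and Acot3 at 1.16, and male-biased genes lower (−0.15, percentile 0.06), with Cyp4a12b at −1.41 and C6 at −0.87, against Selenbp2 at 2.28. NRF2 targets were at 0.24 (percentile 100), led by Cbr3 (1.60), and xenobiotic genes at 0.14 (percentile 100), with Nr1i3 at 0.89. Myeloid markers (0.31), NF-kB targets (0.32) and interferon-stimulated genes (0.19) were higher, with Cd14 at 0.73, Ccl11 at 1.09 and Usp18 at 0.95. Erythroid markers (−0.50) and cytosolic heat shock chaperones (−0.14) were lower, with Klf1 at −0.64 and Bag3 at −0.33.

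The double knockout liver was set against wild-type liver. Tpmt was 16.4-fold higher, Gdpd3 at least 11.4-fold, A2ml1 8.33-fold, Asns 7.76-fold, Cish 6.30-fold, Rgs5 5.88-fold, Igfbp1 5.03-fold, Cd63 4.77-fold, the chemokine Cxcl1 4.70-fold and the trefoil factor Tff3 4.35-fold. Prm1 was at least 15.4-fold lower, Casp9 at least 9.79-fold, Obp2a 7.84-fold, Olig1 7.09-fold, the transcriptional repressor Bcl6 6.77-fold, Crym at least 4.98-fold, Rmdn3 4.78-fold, G0s2, an inhibitor of fat breakdown, 4.25-fold, and Zfp738 at least 3.76-fold. Other probes disagreed for Trim33, 5.35-fold higher by its brightest probe and at −0.42 by another, and for Casp9, at 0.26 by another. In all, 278 of 8955 genes differed at least 2-fold, 143 higher and 135 lower. The count was 53 with no background correction and 152 with arrays scaled to the same median.

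In the double knockout liver 11 lists stood apart. Immediate-early genes had a median of 0.65 (percentile 100), with Dusp1 at 2.06, Fos at 1.80 and Zfp36 at 1.45, and NF-kB targets 0.34 (percentile 99.4), with Cxcl1 at 2.23 and Il1b at 1.07. Of 28 myeloid markers 25 were higher (0.50, percentile 100), led by the class II genes Cd74 (1.93), H2-Ab1 (1.79), H2-Eb1 (1.65) and H2-Aa (1.33). Interferon-stimulated genes were at 0.20 (percentile 99.9), with Psmb8 at 1.12 and Usp18 at 0.84, against Bst2 at −0.75. Of 35 PPARA targets and fatty acid oxidation genes 30 were lower (−0.15, percentile 0.1), with Angptl4 at −1.83, Cyp4a14 at −1.74 and Acot1 at −0.82. Male-biased genes were at −0.17 (percentile 0), with Elovl3 at −1.44, Cyp4a12a at −1.26 and C6 at −1.21, while the female-biased list, at 0.20, stayed within the limits (percentile 91.5). Cholesterol synthesis genes were at 0.15 (percentile 98.7), with Sqle at 1.55, and xenobiotic genes at 0.12, with Cyp2b10 at 1.71. Stellate cell markers were at 0.31 (percentile 99.4), with Rgs5 at 2.56. Erythroid markers (−0.29) and heat shock chaperones (−0.16) were lower, with Klf1 at −0.61 and Bag3 at −0.39.

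Over the pairs of livers that share no array, Nsun2 loss was accompanied by several large differences. Rgs5 rose by 1.67 (SE 0.17, adjusted p 0.00351 by limma over the stellate list alone), the pentraxin Apcs by 1.89 (SE 0.21, adjusted p 0.00631 over the acute-phase list alone), Gadd45g by 1.31 and Ctrl by 0.79, each adjusted over its list alone, while Cyp4a12b fell by 1.35. Olig1, not detected in Nsun2-/-, and Ccn1, detected only on the array labelled Dnmt2-/-, also passed as lower. Rgs5 and A2ml1 were detected in no MEF array. The fit shares its spread over both sample types, so their SE and adjusted p may be too small. Over all genes limma called 0 for Nsun2 loss in liver, with 662 at an unadjusted p under 0.05; the lowest adjusted p were those of Casp9 (−3.37, 0.0797), A2ml1 (3.03, SE 0.22), Prm1 (−3.66, SE 0.27), Tpmt (3.84, 0.209) and Cish (2.85, 0.251), of which Casp9 and Prm1 were not detected by their brightest probes in either liver labelled as lacking Nsun2. In both pairs 18 genes were at least 2-fold higher and 19 lower, with 33 opposite (r 0.082 over 9756 genes), where independent pairs would give 3.54 higher and 7.74 opposite; these included Bcl6 (−1.54 and −2.36) and Mul1 (−2.11 and −1.51). Nsun2 was not detected on the array labelled Dnmt2-/-, which stands on the Nsun2-containing side of this test. In double knockout minus that array, cholesterol synthesis (0.24, percentile 99.95) and xenobiotic genes (−0.13, percentile 0.03) turned round from the Nsun2-/- liver. Fatty acid synthesis (−0.13), clock genes (−0.20), bile acid genes (−0.17), myeloid markers (0.53) and NF-kB targets (0.39) kept their direction past the limits. The other lists described for the Nsun2-/- liver lay within them.

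For Dnmt2 loss in liver, Asns rose by 1.78 (SE 0.25, adjusted p 0.0247 by limma over the ATF4 targets alone), Sqle rose by 1.33 over cholesterol synthesis alone and Derl3, of the endoplasmic reticulum and not detected in either liver labelled as lacking Dnmt2, passed as lower over its list alone. Over all genes limma called 0, with 458 at an unadjusted p under 0.05 and a lowest adjusted p of 0.971; Anln (1.54), Asns, Derl3, Adamtsl2 (−1.18) and Vcpkmt (1.43) had the lowest p. In double knockout minus Nsun2-/- liver, PPARA targets (−0.24, percentile 0) and gluconeogenesis and amino acid catabolism genes (0.08, percentile 98.0) turned round. Female-biased genes (−0.14, percentile 11.6) and the other lists described for the array labelled Dnmt2-/- lay within the limits in that pair. In both pairs 8 genes were at least 2-fold higher and 4 lower, with 29 opposite (r −0.053), against 2.41, 2.60 and 5.11. Besides Asns, Anln, Vcpkmt and Derl3, they included Rgs16 (1.98 and 2.43), Spn (1.28 and 1.34), Emp1 (1.23 and 1.16), Pmepa1 (−1.13 and −1.11), Fgfr1op2 (−2.31 and −1.05) and Lgals4 (−1.04 and −1.12).

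Over both sample types together, 7 interferon-stimulated genes rose with Dnmt2 loss by limma adjusted over the list alone: Psmb8 the most, Cxcl10 by 0.84, Mx2 by 0.81, Ifi204 by 0.79, Ifit3 by 0.78, Oasl2 by 0.74 and Rtp4 by 0.50. Pltp rose by 0.84 over the p53 targets alone. With Nsun2 loss Socs3 rose by 0.93 over the immediate-early genes alone and Ctrl rose by 0.65 over the pancreas markers alone. Over all 10491 genes limma called 0 for Dnmt2 loss (419 at an unadjusted p under 0.05, lowest adjusted p 0.977) and 0 for Nsun2 loss (442 at an unadjusted p under 0.05). Both counts at an unadjusted p lay below the share of 0.05 that no effects would give. So did those for the interaction, Nsun2 loss in MEFs and Dnmt2 loss in liver. For Dnmt2 loss Sorbs3 (0.86), Olfr720 (−0.64), Ifi204, Pltp and Mx2 had the lowest p. For Nsun2 loss they were Fastkd3 (−1.61, adjusted p 0.139), Zfp367 (−1.65, adjusted p 0.149) and Cdk20 (−1.02, adjusted p 0.202), all on the chromosome of Nsun2, then Erdr1 (0.80) and Plekhb1 (0.81). For the interaction of both genotypes limma called 0 genes, with 404 at an unadjusted p under 0.05 and a lowest adjusted p of 0.955, and Ly6c1 (−2.52) passed over the myeloid list alone. Rgs3 (−1.84), Adamts7 (−1.70), Nt5e (−2.03) and Tacr1 (−1.50) had the lowest p for it, with Ly6c1.

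Differences from wild type in MEFs and in liver had correlations near 0 across genes, with r of 0.013 for Dnmt2-/-, 0.011 for Nsun2-/- and 0.013 for the double knockout. For Dnmt2-/-, 6 genes were at least 2-fold higher and 1 lower in both, with 8 opposite, close to the 3.22, 1.41 and 5.25 of independent comparisons; Thbd (1.32 and 1.32), Lrch1 (1.21 and 1.27), H2-T10 (1.16 and 1.28) and Car11 (1.08 and 1.26) were among them. For Nsun2-/-, 5 were higher (2.96 if independent) and 5 lower (1.2 if independent), with 6 opposite (4.54 if independent), among them Saa3 (2.02 and 2.62), Cxcl14 (1.81 and 1.15), Fastkd3 (−1.86 and −1.43), Zfp367 (−1.78 and −1.11) and Bcat1 (−1.16 and −1.09). For the double knockout, 10 were higher and 10 lower, with 18 opposite, against 6.83, 4.91 and 11.7, among them H2-Ab1 (4.31 and 1.79), Cd74 (1.44 and 1.93), Cxcl10 (1.31 and 1.41), Bcat1 (−2.06 and −1.28), Zfp521 (−1.72 and −1.35) and Fabp5 (−1.15 and −1.49). Tests of the difference itself between liver and MEFs called 0 of 10491 genes by limma for either enzyme, with 578 at an unadjusted p under 0.05 for Dnmt2 loss and 549 for Nsun2 loss; Tfap2b (−5.05), not detected in any liver, and A2ml1 (2.97), not detected in any MEF array, had the lowest p.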

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

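Of the tests in this part, the count of genes around Nsun2, the level of Eif2s3y in the livers and the interferon list medians of the other pairs without the wild-type arrays were chosen only after the result was seen.

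A difference between liver and MEFs in the effect of a lost enzyme marked 14 genes, each past limma's threshold when adjusted over its list alone, while 0 of 10491 genes passed over all genes (578 at an unadjusted p under 0.05 for Dnmt2 loss and 549 for Nsun2 loss). Over all effects and lists, 35 of 423 combinations had a gene past this threshold, against 21.2 with no effects, so chance is not excluded for any single gene here. Values are liver minus MEFs on the log2 scale. For Dnmt2 loss the difference was 2.82 for Asns (SE 0.36, adjusted p 0.0144), −2.03 for Irf7 (SE 0.27, adjusted p 0.0239) and 2.28 for Xlr4a (SE 0.44, adjusted p 0.0381). It was 2.41 for Hoxd9, 2.08 for Hoxd8, 1.63 for Hoxa11 and 1.56 for Hoxd4, with adjusted p from 0.00678 to 0.0198. For Nsun2 loss it was 2.14 for Hoxc9 and 1.64 for Hoxc6 (both at an adjusted p of 0.0137), 2.13 for Apcs, 1.67 for Rgs5 and 1.45 for Gadd45g. None of these 6 Hox genes was detected in any liver and Rgs5 was not detected in any MEF array, so for them the difference restates the change in 1 sample type and says nothing on the response of the other. The sex-linked genes Eif2s3y (3.29) and Xist (−1.43) also differed, in step with the sex-linked expression that goes with Nsun2 genotype in the MEFs. Nsun2 was not detected on the liver array labelled Dnmt2-/-, which takes part in all of these differences.

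Interferon-stimulated genes were higher with Dnmt2 loss in MEFs. A low wild-type array alone is argued against by double knockout minus Nsun2-/- MEFs, which leaves that array out and still gave a list median of 0.85. Of the abundant myeloid transcripts chosen in advance, 0 were at least 2-fold higher in both arrays lacking Dnmt2. Tyrobp, Laptm5 and Ptprc were detected on no MEF array and Lyz2 not in Dnmt2-/- MEFs, so these transcripts gave no sign of myeloid RNA in Dnmt2-/- MEFs. RNA of myeloid cells still stays open, because Csf1r and Cd68 have no probe and Lyz2 was higher by at least 0.99 in the double knockout. The myeloid list was at 0.48 in Dnmt2-/- and 0.51 in double knockout MEFs. The interferon list was also higher with Nsun2 loss in both MEF pairs, at 0.23 (percentile 100) and, in double knockout minus Dnmt2-/-, 0.24 (percentile 99.5), so higher values were not confined to Dnmt2 loss, and in the liver pairs for Dnmt2 loss it was 0.13 (percentile 99.4) and 0.06 (percentile 85.7); a difference between the arrays unrelated to genotype stays open.

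Fastkd3, Zfp367 and Cdk20 were lower with Nsun2 loss in both sample types, and all lie on the chromosome of Nsun2, as neighbours 3, 38 and 33 in order of distance among the 363 tested genes there. DNA of another strain carried along with the targeted Nsun2 locus could lower such genes, through a real change or through a probe mismatch, in mice of the mixed background the labels give, and a second probe of Zfp367 was higher by 0.36 in Nsun2-/- MEFs. Of the 100 tested genes nearest to Nsun2, 8 had an unadjusted p under 0.05 against a median of 4 over 8503 windows, which is the 94.6th percentile, short of the 95th that the test asked for; these 8 include the 3 genes that prompted the test, and Ctsl (1.32), Prxl2c (0.68) and Mef2c (0.33) among them were higher. Carried-along DNA and an effect of Nsun2 loss cannot be told apart here, because both follow the genotype labels. Nsun2 was not detected on the liver array labelled Dnmt2-/-. There the 3 genes lay near wild type (Fastkd3 6.41 against 6.13, Zfp367 6.77 against 6.88, Cdk20 7.90 against 7.93). Whether that array lacks Nsun2 is not settled.

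Female-biased genes were higher and male-biased genes lower in the Nsun2-/- liver, and male-biased genes were also lower in the double knockout liver. The largest rise of female-biased genes was on the array labelled Dnmt2-/- (median 0.56, percentile 100, 10 of 10 higher). With the wild-type array left out, the female-biased minus the male-biased list median in double knockout minus that array was −0.16. This value met the condition set in advance for an extreme wild-type array alone. But Nsun2 was detected on neither array of this pair, so the pair may hold no Nsun2 difference. An extreme wild-type array alone and an effect of Nsun2 loss therefore cannot be told apart. A female animal is argued against by Y-linked Eif2s3y, whose lower difference from wild type in these livers was −0.0301. Other sex-linked genes were mixed. Kdm5d was not detected in the Nsun2-/- liver but was 6.05 in the double knockout against 5.75 in wild type. By 1 probe Xist was detected in the 3 knockout livers (5.48, 5.21 and 4.85) and not in wild type. A second Xist probe was detected among the livers only in Nsun2-/- (5.16).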

How the results depend on the processing

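Counts without X and Y genes, fits over a list alone under other settings, and the count of splits of the arrays were chosen only after the result was seen. Under 5 other normalizations 0 of 740 values of named genes changed sign and 667 stayed at least 2-fold. Of 57 differences with another detected probe, 41 were at least 2-fold in the same direction and 6 changed sign: Dppa5a (0.34) and Zfp367 (0.36) in Nsun2-/- MEFs, Fbln2 (0.32) in double knockout MEFs, Apoc2 (1.35) on the liver array labelled Dnmt2-/-, and Trim33 (−0.42) and Casp9 (0.26) in the double knockout liver. Of 442 list medians under alternatives, 410 stayed past the limits, 31 did not and 1 changed sign, gluconeogenesis and amino acid catabolism on the liver array labelled Dnmt2-/- (0.0066 with median scaling). Those that left the limits under at least 1 setting were translation factors, smooth muscle and cell cycle in Dnmt2-/- MEFs, germline genes in Nsun2-/- MEFs, endoplasmic reticulum chaperones, fatty acid synthesis, cytosolic ribosomal proteins, epithelial genes, smooth muscle and p53 targets in double knockout MEFs, aminoacyl-tRNA synthetases and immediate-early genes on the liver array labelled Dnmt2-/-, heat shock chaperones and erythroid markers in the Nsun2-/- liver and stellate markers in the double knockout liver. Germline genes on the liver array labelled Dnmt2-/- had too few members detected on both arrays for a percentile. Of 54 counts of 2-fold genes, 27 moved by more than 1.5 times. In Dnmt2-/-, Nsun2-/- and double knockout MEFs they were 131, 95 and 254 with no background correction, 198, 143 and 365 with an offset of 50, and 133, 94 and 253 with the authors' deposited values. In the livers in the same order they were 32, 44 and 53 with no background correction, 52, 75 and 73 with an offset of 50, 34, 47 and 53 with the authors' deposited values, 99, 147 and 154 with quantile normalization within each sample type, 108, 142 and 152 with median scaling, and 102, 138 and 148 with detection on both arrays. Leaving background in or adding a larger offset shrinks every log2 difference by construction, and asking for detection on both arrays removes genes; for the other settings the cause was not tested. Without X and Y genes the counts were 345, 243 and 638 in MEFs and 206, 252 and 268 in livers. Of 60 limma counts over all genes 1 moved, Dnmt2 loss in MEFs, from 0 to 5 with median scaling, and the cause was not tested; 7 counts for the interaction and 14 for the differences between sample types stayed at 0. Over the list alone, leaving out each MEF array in turn gave 12 to 15 interferon-stimulated genes and 4 to 11 Hox genes for Dnmt2 loss and 2 to 9 Hox genes for Nsun2 loss; these fits have 1 residual degree of freedom and assume that a lone array varies like the others. For Dnmt2 loss and Nsun2 loss over both sample types all 33 splits of the 8 arrays, and for the interaction all 32, gave 0 genes, as the real one did, with 0 as the highest other; beside a real count of 0 this could not come out otherwise and tests nothing. The 42 correlations of pairs under alternatives each moved by less than 0.1, and the 36 counts of lists stayed within 1.5 times. Signal close to background limits what can be seen: 45.2% to 52.4% of probes were detected per array, and differences of dim genes are bounds. No paired analysis was possible because each group has 1 array and the labels give the same replicate number to all of them.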

Other observations

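The medians of gene lists in pairs that leave out the wild-type arrays were examined only after the main results were seen; the other tests in this part were chosen before their results were seen.

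Lists also stood apart between the double knockout and the single knockouts. In MEFs, 40 of 44 extracellular matrix genes were lower in the double knockout than in Dnmt2-/- (median −0.62, percentile 0), while 61 of 66 respiratory chain genes (0.30, percentile 100) and 53 of 68 mitochondrial ribosomal proteins (0.28, percentile 100) were higher. All 23 detected Hox genes were lower in the same pair (−0.70, percentile 0). Against Nsun2-/- MEFs, the double knockout had lower glycolysis and hypoxia targets (−0.39, percentile 0.01), while aminoacyl-tRNA synthetases (0.01, percentile 50.3) and tRNA modification enzymes (0.02, percentile 52.2) stayed in the middle of the random lists. In liver, 18 of 19 cholesterol synthesis genes were higher in the double knockout than in Nsun2-/- (0.57, percentile 100), and NRF2 targets (−0.28, percentile 0) and PPARA targets (−0.24, percentile 0) were lower. Against the liver array labelled Dnmt2-/-, 33 of 35 PPARA targets were lower (−0.34, percentile 0), and acute-phase genes (0.32, percentile 100) and myeloid markers (0.53, percentile 100) were higher.

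Cish was higher by 3.20 and 2.66 and Bcl6 lower at −1.54 and −2.76 in the Nsun2-/- and double knockout livers, with Cish at 0.15 on the array labelled Dnmt2-/-. A recent growth hormone pulse acting through STAT5 may account for this, since growth hormone is released in pulses. Socs2, a STAT5 target chosen for the test before its value was seen, was higher in both livers, and the lower difference was 1.17. Igf1 (−0.07 and −0.22) and Igfals (0.01 and −0.21), which respond more slowly, lay close to wild type. With 1 animal per genotype a pulse in these animals and an effect of Nsun2 loss are not separated by this test.

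The lower clock genes of the Nsun2-/- liver could come from another time of day at collection, which the labels do not give. The 6 detected genes among Dbp, Tef, the Nr1d and Per genes and Ciart had a median of −0.58, with Ciart itself the other way, higher by at least 0.84, and the 3 among Arntl, Npas2, Clock, Nfil3 and Cry1 a median of 0.28. The difference of −0.85 has the direction such a shift would give and is smaller than the 1 asked for, and with so few detected genes it stays open.

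For Dnmt2 loss over both sample types, 7 of the 100 tested genes nearest to Trdmt1 had an unadjusted p under 0.05, against a median of 4 over all windows. This was the 92.4th percentile, so strain DNA carried along with the targeted Dnmt2 locus could neither be shown nor excluded.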
